A study of Danio rerio with 20 samples.

How the data were processed

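The data were 20 arrays with 2 channels, each comparing total RNA from 2 pools of whole zebrafish embryos at 48 h. The groups, concentrations and replicate numbers were taken from the labels. Per the labels, each plate held 20 exposed embryos, 5 plates were run per group, and the survivors of a plate were pooled; RNA was amplified and labelled with Cy3 or Cy5, and every pair of RNA samples was hybridised in both dye orientations.

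The deposited scanner files give a spot intensity per channel, the amplitude that BlueFuse for Microarrays estimated from the image per the file headers (version 3.3 for 2 arrays, 3.6 for 18), with no background column and a confidence grade per spot. The deposited value table gives 1 log2 ratio per spot and array, made by the authors in a way the labels do not state. Each of its 20 columns correlated best with the Cy5 over Cy3 ratio of its own array (Spearman 0.38 to 0.84), which settles its direction. Its column medians lay between -0.04 and 0.07, close to 0, and its normalization, and with it the exact scale, stays unknown.

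Log2 ratios of Cy5 over Cy3 were computed in R 4.3.3 with limma 3.58.1 (statmod 1.5.0 for the pair as a random block), and file lists were read with jsonlite 2.0.0. The amplitudes were taken as already an estimate of signal, which the files do not state in full, so no normexp correction or subtraction was applied. On arrays 3 to 14, the second scan batch, empty spots came close to the probes in at least 1 channel. The median amplitude was 1.33 to 1.65 times that of empty spots in Cy3 on arrays 3 to 8. In Cy5 it was 1.09 to 1.85 times on arrays 9 to 14. In each pair the pool in that channel was the same in both orientations. These pools were DMSO 0.025 ml/L replicates 2, 3 and 4, control replicate 1, DMF 0.025 ml/L replicate 1 and DMSO 0.1 ml/L replicate 3. The background may therefore not be fully removed there, and 2 forms of normexp were tried as alternatives. Ratios were normalized within each array by loess (span 0.3, 4 iterations) with control spots at weight 0. Of 17328 spots per array, 750 control spots were left out, as were spots of the lowest confidence grade (confidence below 0.1); saturated spots were kept. The 172 spots of 1 repeated probe were averaged, giving 16407 probes. Each array's sign was turned one way, and the 2 arrays of a pair were averaged to 1 ratio, in which a dye effect common to both arrays cancels. Background that follows the same pool in both orientations, as may be so in the second scan batch, does not cancel there. A pair's ratio was missing where either array had a low-confidence spot.

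The model had 4 coefficients (each exposed group minus control), was fitted with lmFit and eBayes, and called probes at a Benjamini-Hochberg adjusted p under 0.05. The plan fixed beforehand had all 20 arrays in 10 pairs, with 6 residual degrees of freedom. Array 1, whose file names the scan of array 17, was left out after the data were seen. So 18 arrays in 9 pairs entered, with 5 residual degrees of freedom and 8.67 prior degrees of freedom. Array 2, its partner, had no opposite orientation and also stayed outside. A probe needed a ratio in at least 8 pairs, which 3652 had. Scan batches were read from the scan names: batch 1 held array 2, batch 2 held 12 arrays and batch 3 held 6 arrays of the model. An offset between batches cancels in a ratio taken within 1 array. The 10 comparisons, the F test, the gene lists and the rule for named genes were fixed before the data were examined; the interaction test and the tests of the scan batch, of the spread between pools and of the like arrays were not.

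Gene names were taken by matching RefSeq accessions, without versions, to the reference gene table; 59 probe spots carried such an accession and 47 matched a symbol (0.284% of spots). The other names are mostly GenBank records that no table here pairs with genes, so at most 2 of them are printed per direction. Per comparison against control, named genes were to be up to 10 higher and 10 lower past the threshold, or, where fewer than 5 passed, the 10 of smallest p given as values that did not pass; for the other comparisons the numbers were 5, 5 and 5. No named gene passed in any of the 10 contrasts. Gene lists needed 5 measured members for a test with camera and fry, and no list had them, with or without low-confidence spots.

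The steps from the averaging of pairs on were tested on simulated data with the model's spread and the real missing values. In these data 200 of 3652 probes were changed at once, and loess and the confidence grades were not simulated. At a true log2 change of 1, 90% were recovered for DMSO 0.025 ml/L, 90% for DMSO 0.1 ml/L, 76% for DMF 0.025 ml/L and 94% for DMF 0.1 ml/L; at 0.5 the shares were 24%, 8%, 12% and 16%. In 20 simulated sets with no change, 14 had at least 1 call over the 10 contrasts, 46 calls in all, and the most in 1 contrast was 5. These simulations draw each probe independently. The change was added to the normalized ratio, with the same spread in every pair, while fitted pair weights ran from 0.51 to 2.19. Where a channel lies close to empty spots, a change in RNA may be smaller in the ratio. The shares therefore hold for changes of the ratio and may be too high for changes of RNA. Recovery with fewer changed probes, where the adjusted threshold is stricter, was not simulated.

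Alternatives were print-tip loess, Aquantile between arrays, a filter at the 95th percentile of negative control spots, low-confidence spots kept, single arrays with a dye coefficient (also per scan batch), separate channels, the replicate number as a block, the authors' value table and leaving out each pair. The arrays as deposited, which are the planned 10 pairs, were fitted beside the 9 pairs. So was normexp with offset 50 fitted on all spots, which was planned unless the values were already corrected. Added after the data were seen were an offset of 50 (also with low-confidence spots kept) and both same-scan arrays left out. So were the same normexp with the background from empty and buffer spots, pair weights, the second scan batch alone and the interaction test. Leaving out 1 pair removes 1 pool of each of its groups. Figures were drawn with matplotlib 3.10.9.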

Results

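Gene expression was measured in whole zebrafish embryos at 48 h post fertilisation after exposure to dimethyl sulfoxide (DMSO) or dimethylformamide (DMF), 2 organic solvents that carry poorly soluble chemicals into test water. Each solvent was given at 0.025 and 0.1 ml/L, and unexposed embryos served as controls. The 5 conditions had 4 RNA samples each, and every RNA sample came from the pooled embryos of 1 plate. The samples formed 10 pairs, and each pair was hybridised to 2 arrays with Cy3 and Cy5 exchanged, giving 20 arrays. Every 2 of the 5 conditions met on 1 pair, so a comparison rests on its own pair and on pairs with other conditions. An array held 16578 probe spots, of which 30.0% to 67.4% carried a confidence grade above the lowest. The 12 arrays of the second scan batch kept 35.5% to 51.0% of spots, and the 6 arrays of the last batch that entered the model kept 56.2% to 67.4%. The number of arrays limits the precision.

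The file of array 1 named the scan of array 17, and the raw log ratios of these arrays correlated at 0.90, against at most 0.64 over the other 189 array pairs. Array 1 was therefore left out, which removed the pair of DMSO 0.1 ml/L replicate 1 with DMF 0.025 ml/L replicate 2 from the model. The remaining 9 pairs held 4 pools each of control, DMSO 0.025 ml/L and DMF 0.1 ml/L, and 3 pools each of DMSO 0.1 ml/L and DMF 0.025 ml/L. A ratio in at least 8 pairs was available for 3652 probes, and the 2 arrays of a pair correlated at 0.14 to 0.85 across probes after the dye effect was removed. In the second scan batch the same pool lay close to empty spots on both arrays of a pair. Background may therefore be part of these correlations and of the pair ratios.

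**Figure D1:**
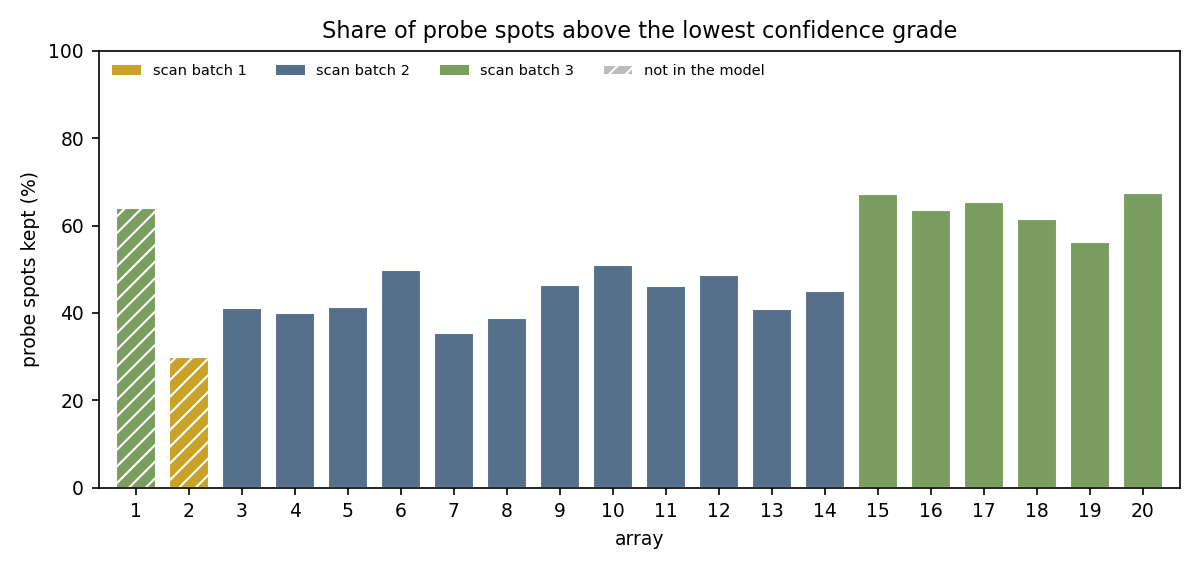
Percent of probe spots kept on each of the 20 arrays (vertical axis) by array number (horizontal axis), with bars coloured by scan batch and hatched where the array did not enter the model. Array 2 kept the lowest share (30.0%) and array 20 the highest (67.4%).

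The deposited probe names are mostly GenBank records of expressed sequence tags, and 47 probe spots could be given a gene symbol. Of these, 14 genes were measured in enough pairs to be tested. The tested genes were the homeobox genes dlx1a, dlx2a, dlx5a, dbx1b, hmx3a, hoxa13b, hoxb1b and hoxb5a, the transcription factors egr1, mafba and zeb1b, the retinoic acid receptor rarga, the insulin-like growth factor receptor igf1rb and naca, which binds nascent peptides. Of the 30 gene lists fixed beforehand, the neural list had 3 tested members (dlx1a, dlx2a and dlx5a) and the retinoid, thyroid and steroid hormone list had 1 (rarga). No list reached the 5 members needed for a test, so the lists for xenobiotic metabolism, oxidative stress, heat shock and the embryonic tissues were not analysed here.

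The comparison of DMSO at 0.1 ml/L with control asked whether the higher concentration of this solvent changes transcripts by itself. In this comparison, 10 probes rose and 0 fell, by a median of 2.28 on the log2 scale (range 1.37 to 3.68), while at an unadjusted p under 0.05 there were 197 higher and 255 lower. All 10 were higher in 3 of the 3 pairs that held a DMSO 0.1 ml/L pool, which is no test, because the probes were picked on these pairs. BM155941 rose by 3.13 ± 0.38 (SE of the fit, adjusted p = 0.00415) and AF180890 rose by 3.68 ± 0.49 (adjusted p = 0.00872). Only DMSO 0.1 ml/L replicate 3 and control replicate 4 shared arrays, and this pair gave 2.34 and 2.78 for these probes. Both probes also differed between pools without DMSO at 0.1 ml/L. DMF 0.1 ml/L replicate 1 over control replicate 3 gave 1.21 and 1.91. DMF 0.1 ml/L replicate 2 over DMF replicate 3 of the lower concentration gave -1.19 and -1.43. At the lower concentration, DMF replicate 4 over DMSO replicate 3 gave 1.17 for BM155941, and AF180890 had no ratio. The other such pairs gave -0.36 to 0.12. No table used here pairs either record, or any of the 10, with a gene symbol. Among the named genes none passed the test. The homeobox gene dlx5a, which acts in forebrain and jaw development, had a log2 change of 0.90 ± 0.40 (adjusted p = 0.379). The ear and lateral line gene hmx3a had 0.48 ± 0.22 (adjusted p = 0.381) and dbx1b, a gene of spinal interneuron progenitors, had 0.32 ± 0.21. The growth factor receptor igf1rb had -0.45 ± 0.28, the posterior gene hoxa13b -0.39 ± 0.26 and the retinoic acid receptor rarga -0.33 ± 0.29. The other named values were 0.21 for hoxb1b, 0.18 for mafba, -0.17 for naca and -0.23 for egr1. The neural list members dlx1a, dlx2a and dlx5a gave 0 calls over all probes and 0 when adjusted over the list alone.

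The count of 10 depended on single pairs and on the processing. It was 0 without the pair of DMSO 0.1 ml/L replicate 4 and DMF 0.1 ml/L replicate 3, 2 without DMSO 0.1 replicate 2 and DMSO 0.025 replicate 2, 2 without DMSO 0.025 replicate 3 and DMF 0.025 replicate 4, 4 without control replicate 1 and DMSO 0.025 replicate 1, and 19 (1 of them lower) without control replicate 4 and DMSO 0.1 replicate 3. It was 3 with print-tip loess (1 lower) and 1 with the arrays as deposited, the planned 10 pairs. It was 16 with single arrays and a dye coefficient (3 lower) and 15 in the second scan batch alone (4 lower). Separate channels, which tested 1488 probes, called 72, with 31 higher and 41 lower, so the calls went both ways there. The count was 1 with the background taken from empty spots, and 0 both with low-confidence spots kept and with the authors' value table.

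**Figure D2:**
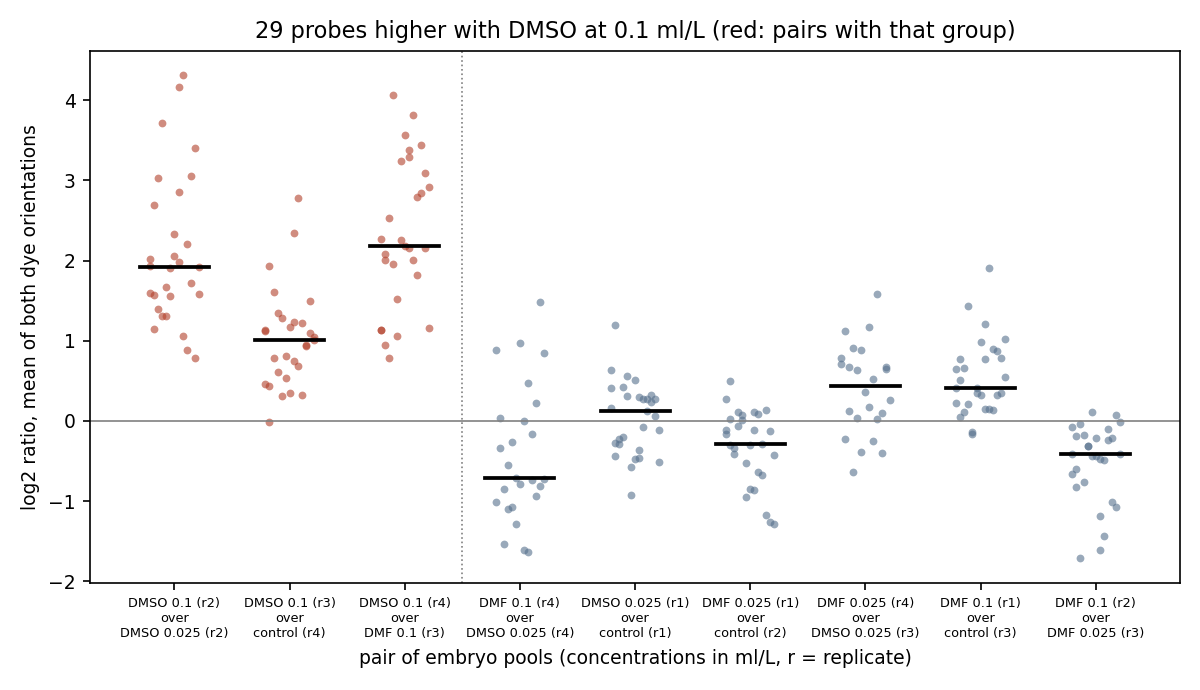
Log2 ratio (vertical axis, mean of both dye orientations) of the 29 probes higher with DMSO at 0.1 ml/L in any of 3 comparisons, for each of the 9 pairs of embryo pools (horizontal axis). Points are probes, lines are medians, and red marks the 3 pairs that held DMSO 0.1 ml/L, with medians of 1.92, 1.01 and 2.18. The medians of the other 6 pairs ran from -0.72 to 0.44. The probes were picked on these data.

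DMSO at 0.1 ml/L was also set against DMSO at 0.025 ml/L, which asked how the effect depends on concentration. Here 15 probes rose and 1 fell, while at an unadjusted p under 0.05 there were 341 higher and 289 lower. The 15 were higher in 3 of 3 pairs with DMSO 0.1 ml/L, on which they were picked, so this is no test. On both of their arrays, DMSO 0.025 replicates 2, 3 and 4 and DMSO 0.1 replicate 3 lay in the channel close to empty spots. Background may therefore enter this comparison, and this was not separated from the solvent. BM155941 rose by 3.61 ± 0.38 (adjusted p = 0.000777) and AF180890 by 3.83 ± 0.50 (adjusted p = 0.00547), and the probe that fell, BI475266, fell by 1.48 ± 0.28 (adjusted p = 0.0317). Among named genes, dlx5a had the largest change, 1.57 ± 0.41, with an adjusted p of 0.117 over all probes and 0.0313 when adjusted over the named genes alone. It was the 1 call among the 3 neural list members when adjusted over the list alone (adjusted p = 0.00671), and 0 of the 3 passed over all probes. The value of dlx5a was 2.2, past the threshold over all probes, without the pair of control replicate 1 and DMSO 0.025 replicate 1. It was 0.73 without the pair of DMSO 0.1 replicate 2 and DMSO 0.025 replicate 2, 0.75 with print-tip loess and 0.56 with the background from empty spots. The posterior gene hoxa13b had -0.75 ± 0.26 (adjusted p = 0.187), hoxb5a 0.61 ± 0.26, the immediate early gene egr1 -0.64 ± 0.29 and hmx3a 0.42 ± 0.22, and none of these passed. The count of 16 became 1 without DMSO 0.1 replicate 2 and DMSO 0.025 replicate 2, 4 without DMSO 0.025 replicate 3 and DMF 0.025 replicate 4, and 4 without DMSO 0.1 replicate 4 and DMF 0.1 replicate 3. It was 26 (3 of them lower) without DMF 0.025 replicate 3 and DMF 0.1 replicate 2, 39 (8 lower) without control replicate 3 and DMF 0.1 replicate 1, 42 (1 lower) without control replicate 1 and DMSO 0.025 replicate 1, and 57 (6 lower) without control replicate 4 and DMSO 0.1 replicate 3. It was 0 with low-confidence spots kept and with the authors' value table, 1 with the background from empty spots and 30 with normexp (1 lower). It was 87 with single arrays and a dye coefficient (20 lower), 147 with separate channels (57 lower) and 35 (13 lower) in the second scan batch, which held all 4 DMSO 0.025 ml/L pools.

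The solvents were compared with each other at matched concentrations. At 0.1 ml/L, 26 probes were lower with DMF than with DMSO and 0 were higher, by a median of -2.08 (range -3.40 to -1.04). Of the 26, 25 had their DMSO pools higher in 3 of 3 pairs, on which they were picked, so this is no test. At an unadjusted p under 0.05 there were 231 higher and 236 lower with DMF. BM155941 was lower by -3.14 ± 0.38 (adjusted p = 0.0040) and AF180890 by -3.40 ± 0.48 (adjusted p = 0.00864). Of the 26, 10 were the probes that rose with DMSO 0.1 ml/L against control, and 12 were among the 15 probes that rose between the DMSO concentrations. The 3 comparisons have the same DMSO 0.1 ml/L pools, so their lists overlap with no effect: in 100 simulated sets without change, lists of these sizes shared a mean of 3.05 (1 to 7) and 3.38 (0 to 8) probes, and independent lists would share 0.0712 and 0.107. The excess over either is not read as a shared effect. Among named genes, igf1rb had 0.43 ± 0.28 and dlx5a -0.58 ± 0.41, with adjusted p of 0.541 and 0.572, and egr1 had 0.40 ± 0.29, mafba -0.25 ± 0.25 and dlx1a 0.20 ± 0.20. At 0.025 ml/L, limma called 0 probes between DMF and DMSO, with 349 at an unadjusted p under 0.05 against 182.6 expected with no change. The homeobox gene dlx5a had 1.06 ± 0.41 at that concentration (adjusted p = 0.488), dlx1a 0.41 ± 0.20, hmx3a 0.40 ± 0.22, mafba -0.36 ± 0.25 and hoxb1b -0.40 ± 0.27, and none passed.

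The count of 26 was 0 without DMSO 0.1 replicate 4 and DMF 0.1 replicate 3, 10 without DMSO 0.025 replicate 3 and DMF 0.025 replicate 4, and 11 without DMSO 0.025 replicate 4 and DMF 0.1 replicate 4. It was 16 without DMF 0.025 replicate 3 and DMF 0.1 replicate 2, 17 (1 of them higher with DMF) without DMSO 0.1 replicate 2 and DMSO 0.025 replicate 2, 60 (5 higher) without control replicate 4 and DMSO 0.1 replicate 3, and 79 (19 higher) without control replicate 3 and DMF 0.1 replicate 1. It was 0 with low-confidence spots kept and with the authors' value table, 2 with the background from empty spots, 4 with print-tip loess (1 higher) and 5 with the arrays as deposited. It was 25 in the second scan batch (5 higher), 57 with single arrays (6 higher) and 88 with separate channels (34 higher). The count of 0 at 0.025 ml/L became 19 without control replicate 1 and DMSO 0.025 replicate 1, where dlx5a (1.70) passed, 3 with single arrays and 38 with separate channels. The 1.06 of dlx5a at 0.025 ml/L was 0.46 without DMSO 0.025 replicate 3 and DMF 0.025 replicate 4, 0.67 in the authors' value table and 0.02 with the background from empty spots.

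Across these 3 comparisons, 29 probes were higher with DMSO at 0.1 ml/L in at least 1, and 9 were called in all 3. Their median log2 change from control was 1.49 with DMSO 0.1 ml/L, -0.17 with DMSO 0.025 ml/L, 0.03 with DMF 0.025 ml/L and -0.40 with DMF 0.1 ml/L. The probes were picked on these data for values above control, DMSO 0.025 ml/L or DMF 0.1 ml/L, so these medians are no test. The value with DMF 0.1 ml/L was -0.89 without control replicate 3 and DMF 0.1 replicate 1, -0.26 without DMSO 0.025 replicate 4 and DMF 0.1 replicate 4, and -0.25 without DMSO 0.1 replicate 4 and DMF 0.1 replicate 3. It was -0.20 without control replicate 2 and DMF 0.025 replicate 1 and -0.10 without control replicate 4 and DMSO 0.1 replicate 3, and -0.08 with the background from empty spots. With 1 pair left out, the value with DMSO 0.025 ml/L ran from -0.50 (without control replicate 3 and DMF 0.1 replicate 1) to 0.08 (without control replicate 4 and DMSO 0.1 replicate 3). The value with DMF 0.025 ml/L ran from -0.19 (without control replicate 3 and DMF 0.1 replicate 1) to 0.21 (without control replicate 2 and DMF 0.025 replicate 1). Within the second scan batch their median change with DMSO 0.1 ml/L was 1.12 over 26 measured probes, and within the last batch it was 2.5 over 29. The same 29 probes also differed between pools that had no DMSO at 0.1 ml/L, with a median of -0.72 for DMF 0.1 ml/L replicate 4 over DMSO 0.025 ml/L replicate 4 and 0.41 for DMF 0.1 ml/L replicate 1 over control replicate 3.

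Against control, DMSO at 0.025 ml/L gave 0 called probes in limma, with 162 at an unadjusted p under 0.05, beside 182.6 expected with no change. The anterior-trunk gene hoxb5a had a log2 change of -0.48 ± 0.25, igf1rb -0.46 ± 0.26 and dlx5a -0.67 ± 0.40. On the positive side, egr1 had 0.41 ± 0.26, hoxa13b 0.36 ± 0.24, dlx2a 0.30 ± 0.19, zeb1b 0.18 ± 0.21 and dbx1b 0.11 ± 0.21. The receptor rarga had -0.14 ± 0.27 and naca -0.10 ± 0.23. The smallest adjusted p among the named genes was 0.996, and 0.388 when adjusted over them alone. For the mean of both DMSO concentrations limma called 0 probes, with 193 at an unadjusted p under 0.05 (182.6 expected), and igf1rb (-0.45 ± 0.23) and hmx3a (0.27 ± 0.18) had the smallest p among named genes. Separate channels called 1 probe in each of these comparisons, and the second scan batch alone called 4 for DMSO 0.025 ml/L and 3 for the mean.

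DMF against control asked the same of the other solvent. At 0.025 ml/L, hmx3a had a log2 change of 0.46 ± 0.22 (adjusted p = 0.801), dlx1a 0.36 ± 0.20, hoxb1b, a hindbrain patterning gene, -0.36 ± 0.27, the hindbrain gene mafba -0.30 ± 0.25 and hoxa13b 0.31 ± 0.26. At 0.1 ml/L, hmx3a had 0.33 ± 0.20, dlx5a 0.33 ± 0.40, dbx1b 0.27 ± 0.19, dlx2a 0.21 ± 0.19 and dlx1a 0.20 ± 0.19. For the mean of both concentrations, hmx3a had 0.39 ± 0.18, with an adjusted p of 0.993 over all probes and 0.628 over the named genes alone, and dlx1a had 0.28 ± 0.17. Of the neural list, dlx1a, dlx2a and dlx5a gave 0 calls at either DMF concentration, over all probes and when adjusted over the list alone.

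In limma, 0 probes were called with DMF at 0.025 ml/L, 0 at 0.1 ml/L and 0 for the mean, with 231, 37 and 141 probes at an unadjusted p under 0.05, each beside 182.6 expected with no change. Separate channels called 3, 2 and 3 probes and the second scan batch alone 3, 2 and 3. The median 95% confidence interval of a probe reached 0.49 on either side at 0.025 ml/L and 0.45 at 0.1 ml/L. In simulated data with 200 probes changed at once, 76% and 94% of probes with a true log2 change of 1 were recovered. At a true change of 0.5 the shares were 12% and 16%. These changes were added to the normalized ratio, so signal close to empty spots was not simulated. Recovery of a change of the same size in RNA may be lower. With fewer changed probes the adjusted threshold is stricter, and recovery was not simulated.

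**Figure D3:**
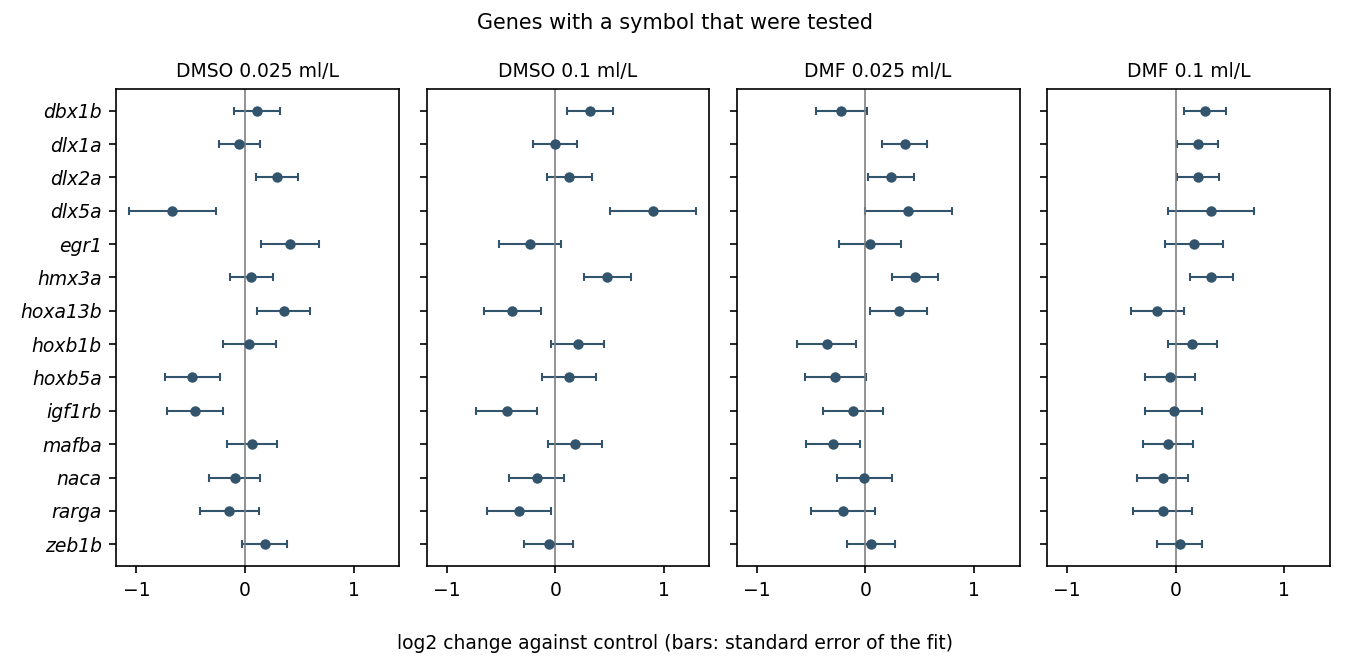
Log2 change against control (horizontal axis, points with the SE of the fit as bars) of the 14 tested genes with a symbol (vertical axis), in 1 panel per exposure. None passed the test in any panel, and dlx5a had both the lowest value (-0.67, DMSO 0.025 ml/L) and the highest (0.90, DMSO 0.1 ml/L).

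Between the DMF concentrations, dbx1b had a log2 difference of 0.49 ± 0.23, hoxb1b 0.51 ± 0.26, hoxa13b -0.48 ± 0.26, mafba 0.23 ± 0.25 and hoxb5a 0.23 ± 0.27 (0.1 minus 0.025 ml/L), and none passed (smallest adjusted p = 0.997). In limma 0 probes were called, with 102 at an unadjusted p under 0.05 (182.6 expected with no change), and the second scan batch alone called 1. The test of whether the step from 0.025 to 0.1 ml/L differed between the solvents, added after the data were seen, called 12 probes, all with a lower value for DMF; with separate channels it called 118, of which 44 had a higher value for DMF. The F test over the 5 conditions called 4 probes, all among those called in the comparisons with DMSO at 0.1 ml/L. The interaction count ran from 0 (without DMSO 0.1 replicate 4 and DMF 0.1 replicate 3, and without DMSO 0.025 replicate 3 and DMF 0.025 replicate 4) through 1 (without DMSO 0.1 replicate 2 and DMSO 0.025 replicate 2) and 2 (without DMF 0.025 replicate 3 and DMF 0.1 replicate 2) to 21 (without control replicate 1 and DMSO 0.025 replicate 1), 32 (1 of them higher, without control replicate 4 and DMSO 0.1 replicate 3) and 45 (13 higher, without control replicate 3 and DMF 0.1 replicate 1). The F count was 0 without each of the 3 pairs named first, and 1, 10, 16 and 30 without DMSO 0.025 replicate 4 and DMF 0.1 replicate 4, control replicate 1 and DMSO 0.025 replicate 1, control replicate 4 and DMSO 0.1 replicate 3, and control replicate 3 and DMF 0.1 replicate 1. Both counts were 0 with print-tip loess, with the background from empty spots, with low-confidence spots kept and with the authors' value table.

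Across the 3652 probes, which are not independent replicates, the log2 changes against control of the 2 DMF concentrations correlated at r = 0.55, beside 0.46 in simulated unchanged groups with the same controls. The 2 DMSO concentrations correlated at 0.10, beside 0.45 simulated. At 0.1 ml/L, DMSO and DMF correlated at 0.13 (0.46 simulated), and at 0.025 ml/L at 0.24 (0.43 simulated). DMSO 0.025 with DMF 0.1 ml/L gave 0.28 (0.49 simulated), and DMSO 0.1 with DMF 0.025 ml/L 0.23 (0.27 simulated). The covariance minus its simulated value was 0.00427 for DMF, -0.0163 for DMSO, -0.0160 between the solvents at 0.1 ml/L, -0.00707 at 0.025 ml/L, -0.0126 for DMSO 0.025 with DMF 0.1 ml/L and 0.0085 for DMSO 0.1 with DMF 0.025 ml/L. With the controls split, these 6 correlations were, in this order, -0.22, -0.29, -0.25, -0.26, -0.24 and -0.18, beside 0.03, 0.03, -0.20, -0.21, -0.03 and -0.44 simulated. The mean of the 6 correlations was 0.26 (0.43 simulated), but 0.48 without control replicate 2 and DMF 0.025 replicate 1 and 0.45 without control replicate 4 and DMSO 0.1 replicate 3.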

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

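The tests of the scan batch, of the spread between pools and of the 2 like arrays, and the test of the difference between the concentration steps, were chosen after the result was seen; the counts of other splits were chosen before, and the test on the array outside the model before its own value was seen but after array 1 was left out and the 29 probes were called.

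Of 45 groups of 4 pools (14 named genes and 3 printed probes, where measured), 4 had a pool far from the others, where chance gives about 2.25. For egr1, control replicate 1 had a level of -0.83 against 0.16 to 0.33 in the other control pools (gap over range 0.858). For egr1, DMSO 0.025 ml/L replicate 2 had 1.58 against -0.41 to -0.11 (gap over range 0.851). For mafba, control replicate 1 had -0.38 against 0.22 to 0.33 (0.842), and DMSO 0.025 ml/L replicate 3 had -0.27 against 0.16 to 0.23 (0.865).

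A direct test of the solvents at 0.1 ml/L called 26 probes, lower with DMF, and the interaction test of the step from 0.025 to 0.1 ml/L called 12. Both counts were 0 without DMSO 0.1 replicate 4 and DMF 0.1 replicate 3, and for the 26 chance was not excluded (below). In the array outside the model, DMSO 0.1 ml/L replicate 1 over DMF 0.025 ml/L replicate 2, the 15 measured members of the 29 probes higher with DMSO 0.1 ml/L had a median log2 ratio of 0.84, and 14 were above 0. This array kept the lowest share of spots (30.0%) and was alone in its scan batch, so its dye correction came from other batches. Its median amplitude was 1.55 times that of empty spots for the DMF pool and 7.41 times for the DMSO pool.

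The 29 probes moved together in the 3 pairs with DMSO at 0.1 ml/L, by medians of 1.92, 1.01 and 2.18, but they were picked on these pairs. Scan batch was not excluded. The 50 probes of smallest p that rose in the second batch had a median change of 1.76 in the last batch. Their rise as a set was therefore not confined to the second batch. The bound from random sets of like intensity was 0.16, but bounds of this kind were too narrow for probes that move together (below). The last batch also left no residual degrees of freedom, so its value came with no test. Chance values of the 3 pools stay open, although the median of 0.84 in the outside array exceeded random sets (0.24), as did 0.53 without dye correction (0.19): the same members had a median of -0.72 for DMF 0.1 ml/L replicate 4 over DMSO 0.025 ml/L replicate 4, where the sign follows the order of the pools, so the bound from random sets, written beforehand, was too narrow for probes that move together, and 1 array decides little. Spread between embryo pools apart from the solvent also stays open, because of 1 of 3 held-out pairs. The 30 probes picked in the other DMSO 0.1 pairs had medians of 1.69 (29 of 30 above 0), 0.78 (27 of 30) and 2.12 (30 of 30) in the held-out pair, and their largest medians, sign aside, over pairs without DMSO 0.1 ml/L were 0.64, 0.62 and 0.63, which is 0.38, 0.79 and 0.30 of the former. The largest of these swings over the smallest held-out median, taken from different sets of 30, was 0.824, above the bound of 0.5. A response to DMSO at 0.1 ml/L may account for the pattern as well, a hypothesis these 4 pools cannot settle.

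The arrays labelled 1 and 17, which carry different samples, had nearly equal values. One scan under both labels may account for this, since their raw log ratios correlated at 0.901, against 0.643 for the next highest of all array pairs. Array 1 holding the RNA of its label is argued against by its correlation of -0.135 with its dye-swap partner, where the pairs in the model had 0.14 to 0.85. Array 17 and its own partner had 0.63. The value of -0.135 is limited, because arrays 1 and 2 lay in different scan batches, unlike the pairs in the model, and array 2 kept 30.0% of spots. A low correlation could arise from this as well. No biological explanation was tested.

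Regrouping the pools of each comparison within the model gave no result for which chance could be excluded. For DMSO 0.1 ml/L against control, 4 of 35 splits called at least the real 10 probes, and the highest other called 43, with DMSO 0.1 replicate 3 and control replicate 2 exchanged. Between the DMSO concentrations 2 of 35 splits called as many as the real 16 (highest other 18, with DMSO 0.025 replicate 1 placed beside the DMSO 0.1 pools). For DMF against DMSO at 0.1 ml/L it was 2 of 35 (real 26, highest other 135, with DMF 0.1 replicate 1 beside the DMSO 0.1 pools). In these last 2 comparisons the other split, and for DMSO 0.1 ml/L against control 2 of the 3 other splits (29 and 10 calls), kept all 3 DMSO 0.1 pools on one side, so they carried most of the real difference. A count several times the real one, such as 135, points to a structure of the pools; here that includes the labelled difference, and no test separated it from another source. For the F test, 6 of 98 random regroupings called at least the real 4 (highest other 10).

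Where no probe was called by limma, the number at an unadjusted p under 0.05 was counted. DMSO 0.025 ml/L against control gave 20 of 35 splits with at least the real 162 (highest other 413), DMF 0.025 ml/L 16 of 35 (231, highest other 497) and DMF 0.1 ml/L 30 of 35 (37, highest other 421). For the mean of both DMSO concentrations it was 39 of 100 (193, highest other 872, which also called 284 probes after adjustment and set DMSO 0.025 replicates 2, 3 and 4 and control replicate 3 against the rest, all 3 DMSO 0.1 pools among them, so the difference between the DMSO concentrations is part of it), and for DMF 56 of 97 (141, highest other 565). DMF 0.1 against 0.025 ml/L gave 18 of 35 (102, highest other 297) and DMF against DMSO at 0.025 ml/L 7 of 35 (349, highest other 632). The highest other counts for DMF 0.1 ml/L and for both means are several times the real ones, which points to a structure of the pools whose source was not tested. The splits with 872 and 632 set DMSO 0.025 replicates 2, 3 and 4 apart from replicate 1. These were the DMSO 0.025 pools in the channel close to empty spots on both arrays. Control replicate 1 and DMSO 0.1 replicate 3 (872) and DMF 0.025 replicate 1 (632) also lay in such a channel but were on the other side. Background may therefore be a part of it.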

How the results depend on the processing

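The arrays as deposited (10 pairs) were the planned set, and normexp with offset 50 was planned unless the deposited values were already corrected. The main fit on 9 pairs was chosen after the data were seen. So were both same-scan arrays left out, the offset of 50, normexp with the background from empty spots, pair weights, the second scan batch alone and the interaction test. Counts of called probes are given in the order DMSO 0.1 ml/L against control, DMSO 0.1 against 0.025 ml/L, DMF against DMSO at 0.1 ml/L, F test and interaction, where they were 10, 16, 26, 4 and 12. Print-tip loess gave 3, 16, 4, 0 and 0. Low-confidence spots kept, the same with an offset of 50, the authors' value table and the replicate number as a block each gave 0, 0, 0, 0 and 0. In limma the probes at an unadjusted p under 0.05 then numbered 251, 869, 209, 150 and 335 with low-confidence spots kept, 254, 815, 223, 142 and 341 with the offset too, 936, 953, 827, 604 and 880 in the value table, and 241, 423, 311, 239 and 177 with the block, where no change gives 820.35 of the 16407 probes tested in the first 3 settings and 162.65 with the block; the F test and interaction had 415 and 571 with print-tip loess. Keeping low-confidence spots and using the value table both test 16407 probes in place of 3652, and the block leaves fewer degrees of freedom; beyond that the cause was not tested. Single arrays with a dye coefficient gave 16, 87, 57, 37 and 36, and 1 for DMF 0.025 ml/L against control and 3 for DMF against DMSO at 0.025 ml/L; with the dye coefficient per scan batch they gave 13, 45, 40, 26 and 26, and 3 for the last named. Separate channels, which count both arrays of a pair as independent, gave 72, 147, 88, 116 and 118; they also gave 1 and 1 for DMSO 0.025 ml/L and the DMSO mean, 3, 2 and 3 for DMF at 0.025, at 0.1 ml/L and their mean, and 38 for DMF against DMSO at 0.025 ml/L. The arrays as deposited gave 1, 11, 5, 1 and 4. Both same-scan arrays left out gave 8, 39, 79, 30 and 45, and 1 each for DMF 0.025 ml/L and the DMF mean. With array 1 already out, this is the same fit as leaving out the pair of control replicate 3 and DMF 0.1 replicate 1. The offset of 50 gave 11, 25, 26, 9 and 12, normexp with offset 50 gave 11, 30, 20, 3 and 11, the same with the background from empty spots gave 1, 1, 2, 0 and 0 (247 and 338 for the last pair at an unadjusted p under 0.05, 182.6 expected), and pair weights 15, 26, 49, 17 and 30. The second scan batch alone (6 pairs, 2 residual degrees of freedom) gave 15, 35, 25, 40 and 16, with 4 for DMSO 0.025 ml/L, 3 for DMF 0.025 ml/L, 2 for DMF 0.1 ml/L, 3 and 3 for the DMSO and DMF means, 1 between DMF concentrations and 3 for DMF against DMSO at 0.025 ml/L; the last batch has 3 pairs and no degrees of freedom, so it gave values with no test.

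Leaving out 1 pair gave 0 to 19, 1 to 57, 0 to 79, 0 to 30 and 0 to 45 probes, 0 to 1 for DMF 0.025 ml/L and for the DMF mean, 0 to 19 for DMF against DMSO at 0.025 ml/L, and 0 for the other comparisons. Without DMSO 0.1 replicate 4 and DMF 0.1 replicate 3 the counts for DMSO 0.1 ml/L against control and for DMF against DMSO at 0.1 ml/L were 0. Of the 29 probes, 9 were measured with separate channels, 24 with the block, 26 in the second batch and 29 in the other settings. Over the 27 settings, which are not all different fits, their medians with DMSO 0.1 ml/L against control were 1.12 to 2.18. With DMF against DMSO at 0.1 ml/L their medians were -2.42 to -1.47, although the probes were picked on these data. Against control, 28 of the 29 were above 0 with print-tip loess, and 28 with the value table. Their medians against control were -1.12 to -0.08 with DMF 0.1 ml/L, -0.50 to 0.08 with DMSO 0.025 ml/L and -0.37 to 0.21 with DMF 0.025 ml/L; the picking favoured low values with DMF 0.1 and DMSO 0.025 ml/L, so these signs say nothing about an effect. The mean correlation of log2 changes between the comparisons against control was 0.26 (0.43 simulated with no change), 0.19 to 0.48 with 1 pair left out and -0.24 with the controls split (-0.14 simulated). Of 2002 recomputed values of named genes, 93 took the other sign, and 2 passed the threshold, both dlx5a.

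Replicate numbers did not pair the pools: the 37 correlations of like-numbered pools not sharing an array had a median of -0.003 (-0.42 to 0.37), and 5 of 20 pools matched best with their own number, so the block is given only here; with it, dlx5a for DMF against DMSO at 0.025 ml/L was -1.0. Aquantile leaves ratios unchanged and the filter on negative control spots removed no tested probe, so these say nothing about stability. No background column exists, so background could be corrected only from the amplitudes themselves, as above. With the background from empty spots the median of the 29 probes with DMSO 0.1 ml/L against control was 1.27, beside 1.49, and why the counts fell was not tested. Gene lists stayed at 0 tested. Signal limits the rest: over the arrays the median amplitude was 1.33 to 12.2 times that of empty spots in Cy3 and 1.09 to 37.4 times in Cy5. Probes without a confident spot in 8 pairs were not tested.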
